A study of Mus musculus with 6 samples.

How the data were processed

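RNA of 3 kidney samples of transgenic mice and 3 of control mice was profiled by sequencing on an Illumina HiSeq 2500, per the labels. Per the labels' protocols, whole kidneys were halved and frozen, RNA was purified on columns, and libraries followed the standard Illumina procedure. Per the submitters' processing notes the genome build was mm10. The aligner, the counting program and their versions are not given in the sources used here.

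The authors deposited 1 table with 24 columns of per-sample values, of which 12 belong to the samples analysed. The other 12 columns of per-sample values were not used, since their names match none of these samples. Per the file headers, genes were kept where at least 2 of 6 samples before ischemia-reperfusion had a value called NRPKM between 5.0 and 84233.281. Genes low in every kidney, or in all but 1, are therefore not part of these results. The deposited raw columns hold estimated counts: they are not whole numbers, and between 41.5% and 53.5% of the values under 3000 are multiples of 1/75 within a tolerance of 0.02, as when reads are counted in fractions. The deposited normalized columns hold log2 values: tested on the table, they equal the log2 of the estimated count divided by 1 factor per library, minus 1 baseline per gene. They were used only for 1 alternative. Of the 7373 rows, 7354 were matched by gene ID to the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, from which chromosomes and positions were taken.

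Estimated counts were rounded to whole numbers. Groups were taken from the genotype labels. The depth was 23.5 to 47.6 M estimated counts per library over the listed genes, with medians per gene of 1205 to 2362 counts. Kap alone took between 4.50% and 5.41% of the counts and the 10 most abundant genes between 13.8% and 16.3%. No pair of libraries looked like 1 library deposited in duplicate: the chi-square per degree of freedom over the 7195 genes outside X and Y was between 23.3 and 152 for all pairs.

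The main test was the edgeR (version 4.0.16, R 4.3.3) quasi-likelihood test with group as the only term, after filterByExpr, which removed 1 gene, and TMM normalization. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Levels are CPM, computed here from the estimated counts with TMM library sizes. With 3 samples against 3, an exact permutation test of a single gene cannot go below p = 0.1, so genes rest on the model fitted across genes. All tests were two-sided. Gene lists were tested with camera (limma version 3.58.1) at a preset correlation of 0.01, adjusted over the 29 lists with at least 4 measured members, out of 37 lists. Camera compares a list with other genes.

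The groups, the tests, the lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The rule took up to 12 genes in each direction past the threshold without overlap between groups, filled up to 6 by the smallest p-value where fewer passed. It added Cryab, Havcr1, Lcn2, Ren1, Fkbp5 and the sex check genes, every list member past the threshold over all genes, and up to 4 members with the smallest p-values in each called list. Akr1b7, Psca and other list members outside this rule are named to give the content of their lists and were chosen after their values were seen. Of what the rule takes, 1 gene and the call of 1 gene list are not described in this text.

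The settings fixed in advance were DESeq2 size factors, no filter, a stricter filter, DESeq2 (version 1.42.0), limma with array weights, the replicate number as a block, leaving out each library, 1 row per gene, other thresholds, camera with an estimated correlation, and fry. The X and Y genes at 0 in control 3 were seen before any test, and leaving them out was added then, alone and with a robust prior, DESeq2, the block, each library left out, a spline correction for GC content and transcript length per library, and limma on the authors' log2 values. A list of renin cell and vascular smooth muscle genes and a list of glomerular genes were added after the gene results were seen. GC content was known for 99.7% of the rows. In the edgeR fit of all genes the biological coefficient of variation was 0.259 and the prior degrees of freedom were 2.40; with X and Y genes left out they were 0.133 and 4.44.

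The analysis was tested on simulated data, with counts drawn for 7372 genes from the means, library totals and dispersions of these kidneys and 200 genes changed in each of 5 runs, for 3 libraries against 3. The edgeR test recovered 98.8% of 2.4-fold changes and 56.8% of 1.5-fold changes in complete counts. With the X and Y genes of control 3 set to 0 it recovered 94.8% and 24.4%, and with those genes left out (7194 genes) 98.8% and 56.8%. In simulated counts those zeros alone cut the mean prior degrees of freedom from 12.4 to 3.26. The zeros can therefore weaken the edgeR test of all genes by themselves. Fits of simulated counts had more prior degrees of freedom than the real fit, 12.1 against 4.44 with X and Y genes left out. The distance of control 3 from the other libraries was not simulated. These shares may therefore be too high for the real libraries. Of the genes called, 5.67% were unchanged ones with edgeR on complete counts and 13.6% with DESeq2 with X and Y genes left out. Camera at the preset correlation called 0 of 100 simulated unchanged lists, whose genes were drawn independently of one another, and 5 of 5 lists shifted by -0.4 on the log2 scale. That shift is larger in size than the median of any list called in the test of all genes. Smaller shifts of lists were not simulated. Tables were read with pandas 2.3.3 and plotted with matplotlib 3.10.9 in Python 3.11.15.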

Results

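Messenger RNA was sequenced from kidneys of adult male FVB/N mice, an inbred laboratory strain. The transgenic mice, source of 3 samples, overexpressed CryAB, a small heat shock protein, with the R120G mutation. They did so in heart muscle cells under the promoter of α-myosin heavy chain, and were sampled before heart failure began. The control mice, source of the other 3 samples, were matched for age and sex. Frozen pieces of whole kidney were used, so each library mixes cortex and medulla. The table lists 7373 genes, and its estimated read counts add up to 28.0, 34.9 and 47.6 M in controls 1, 2 and 3 and to 29.0, 23.5 and 31.7 M in transgenic kidneys 1, 2 and 3. The labels describe triplicates of kidneys and do not number the animals, so p-values measure the spread between these samples.

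Control 3 differed from the other 5 libraries in 1 respect that bears on all tests. All 178 listed genes of chromosomes X and Y, 176 on X and 2 on Y, were listed at 0 in control 3, and none of the other 7195 genes was at 0 there. In the other 5 libraries all 178 were above 0 and took between 1.90% and 2.02% of the counts. Among them was Eif2s3y, a Y-linked translation factor gene, at 49.7 and 58.2 CPM in controls 1 and 2, at 0 in control 3, and at 57.9, 63.8 and 55.8 in the transgenic kidneys. Control 3 also stood apart in the remaining genes, at 24.7 on a first principal component that held 51.9% of the variance, where the other libraries lay between -12.5 and 0.71. Fold changes of X and Y genes are not interpreted here.

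**Figure D1:**
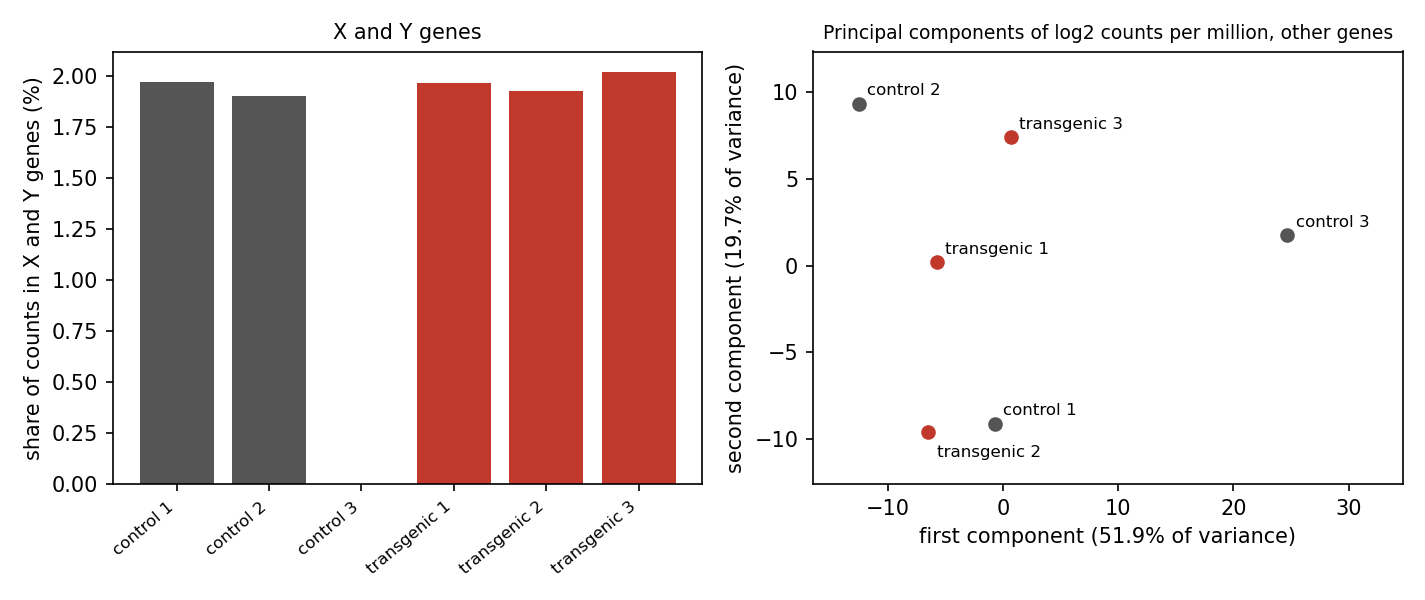
Left, the share of each library's estimated counts in genes of chromosomes X and Y, in percent; control 3 is at 0 and the other 5 libraries lie between 1.90% and 2.02%. Right, the scores of the 6 libraries (grey control, red transgenic) on the first and second principal components of log2 CPM over the other genes, with control 3 at 24.7 on the first.

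The endogenous gene of the overexpressed protein was read first. Cryab (gene ID 12955; chromosome 9, 50745951 to 50756636, mm10) stood at 207, 220 and 288 CPM in the control kidneys and at 183, 175 and 191 in the transgenic kidneys. The means were 238 ± 43.4 (SD, n = 3) in controls and 183 ± 7.76 (SD, n = 3) in transgenic kidneys, a log2 fold change of -0.38 ± 0.13 (SE). The groups did not overlap, but the difference did not pass the test (adjusted p = 0.997, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without control 3 the log2 fold change was -0.22.

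The main comparison asked which kidney transcripts differ in mice with a heart muscle disease that has not yet led to heart failure. Ren1, which encodes renin, the protease that starts the renin-angiotensin cascade, was higher in all 3 transgenic kidneys than in all 3 controls. It stood at 293, 338 and 247 CPM in the control kidneys and at 734, 716 and 645 in the transgenic kidneys, a 2.38-fold difference (log2 fold change 1.25 ± 0.13, SE). Ptger3, which encodes the prostaglandin E2 receptor EP3 of the thick ascending limb, was lower in all 3, at 53.6 ± 3.81 CPM (SD, n = 3) in controls and 40.03 ± 2.28 (SD, n = 3) in transgenic kidneys (log2 fold change -0.42 ± 0.09, SE), and did not pass the test. The median log2 fold change of all genes was 0.00, but normalization centres this value, so it does not measure the size of the differences. The further genes described from those with the smallest p-values differed by at most 1.02 on the log2 scale.

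**Figure D2:**
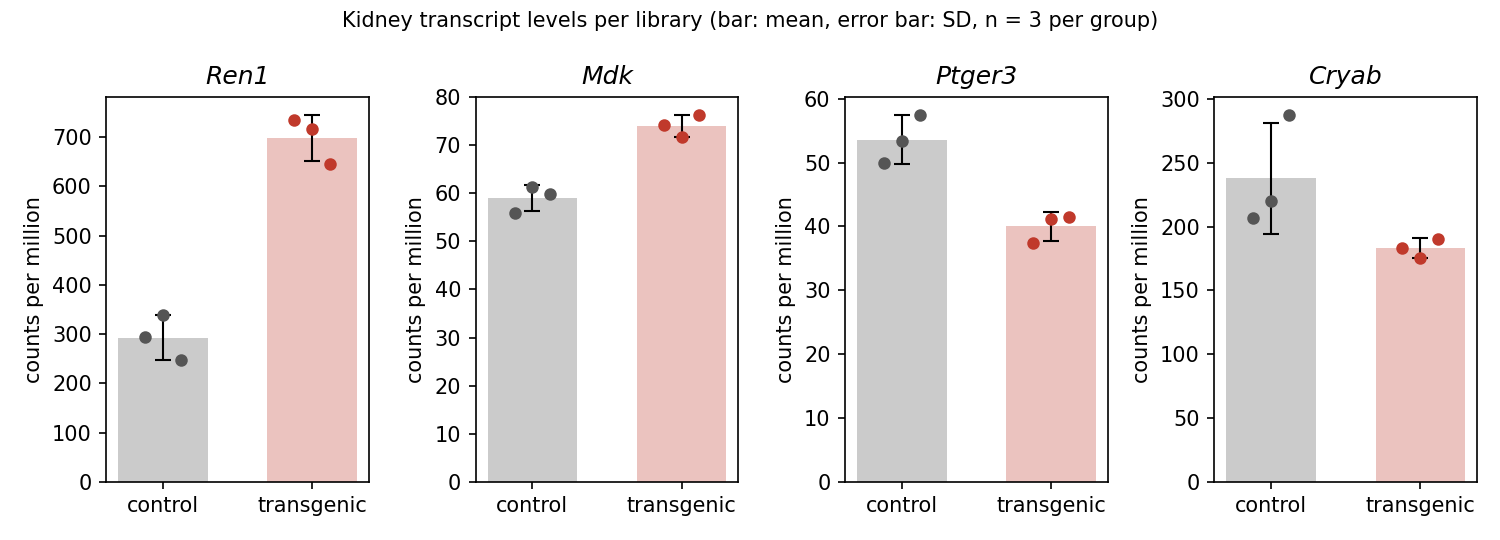
CPM of Ren1, Mdk, Ptger3 and Cryab in each library (points), with group means (bars) and SD (error bars, n = 3 per group). The 3 transgenic kidneys lie between 645 and 734 for Ren1 and the 3 controls between 247 and 338; for Ptger3 and Cryab the transgenic kidneys lie below the controls.

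None of 7372 genes passed an adjusted p of 0.05 with the edgeR quasi-likelihood test, and 112 had an unadjusted p under 0.05. Ren1 (gene ID 19701; chromosome 1, 133350674 to 133360320, mm10) had an adjusted p of 0.348 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. With the X and Y genes left out, an alternative chosen on seeing their zeros, Ren1 rose at an adjusted p of 0.0359 (edgeR quasi-likelihood test) and was the 1 gene called out of 7194, where 131 had an unadjusted p under 0.05 and chance alone gives 359.7. DESeq2 on all genes called 2 genes, Ren1 among them (adjusted p = 3.02e-16). Across all 26 alternatives the log2 fold change of Ren1 stayed between 1.14 and 1.37, while its adjusted p ranged from 2.35e-16 to 0.9999 and passed the threshold in 12 of them. With the X and Y genes left out, the call of Ren1 was lost without control 1 (adjusted p = 0.431, edgeR), without transgenic kidney 1 (0.365), 2 (0.392) or 3 (0.178). Reads of Ren2, a closely similar copy carried by some mouse strains, would be counted under Ren1 if present, so the share of each copy is uncertain.

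Genes that the rule took among those higher in transgenic kidneys were Mdk, a heparin-binding growth factor (log2 fold change 0.33), Nab2, a co-repressor of EGR transcription factors (0.44), Clic3, of the chloride intracellular channel family (1.02), and Rras, a small GTPase (0.30). Clic3 was low, at 2.57 ± 0.416 CPM (SD, n = 3) in controls and 5.21 ± 1.25 (SD, n = 3) in transgenic kidneys. Among those lower were Ptger3 (log2 fold change -0.42), Serpina1b, an α1-antitrypsin gene (-0.90), and Arg2, the mitochondrial arginase (-0.61). Mturn (-0.40), the ubiquitin ligase gene Wwp1 (-0.27) and the matrix protein gene Spon1 (-0.40) were lower too. In each of these genes and in Ren1 the 3 transgenic values did not overlap the 3 control values, and with edgeR each except Ren1 had an adjusted p of 0.997. Serpina1b has near-identical neighbours that can share its reads. Over the 7194 genes outside X and Y, 213 were higher and 217 lower in all 3 transgenic kidneys without overlap, together 5.98%, where chance gives 10%.

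Among markers of kidney cell types, 4 lists fixed before the data were examined lay lower in transgenic kidneys than other genes did, by camera with a preset correlation of 0.01. No member of these 4 lists passed the test over all genes. Of the 12 measured genes of the androgen-responsive list, male-biased transcripts of the proximal tubule, 10 were lower, with a median log2 fold change of -0.19 (camera adjusted p = 0.00330; adjusted p = 0.459 with an estimated correlation). They included the 11β-hydroxysteroid dehydrogenase gene Hsd11b1 (-0.54), Acsm3 (-0.46), Slc22a30 (-0.26) and Cyp2j13 (-0.19), while the most abundant, Kap, the kidney androgen-regulated protein, differed by -0.10. Leaving out 1 library moved these values: Hsd11b1 was -0.27 without control 1 and -0.83 without control 2, Slc22a30 -0.40 without control 2, Acsm3 -0.27 and Slc22a30 -0.12 without control 3, and Cyp2j13 -0.11 without transgenic kidney 1. Of the 10 thick ascending limb genes 9 were lower, with a median of -0.08 (camera adjusted p = 0.0103; adjusted p = 0.459 with an estimated correlation). Besides Ptger3, these were led by Cldn16 (-0.27), a tight junction gene, the potassium channel gene Kcnj1 (-0.15) and Cldn10 (-0.10). Kcnj1 and Cldn10 were -0.23 and -0.15 without control 2 and -0.06 and -0.01 without control 3, and Cldn10 was -0.06 without transgenic kidney 1. Ptger3 was the 1 member past the threshold adjusted over the list alone.

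Of the 11 inner medulla and osmolyte genes 10 were lower, with a median of -0.09 (camera adjusted p = 0.0103; adjusted p = 0.459 with an estimated correlation). Beside Cryab, which is on this list too, S100a6 (-0.42), the aldose reductase gene Akr1b3 (-0.23) and Fabp3 (-0.17) had the smallest p-values. Without control 3 S100a6, Akr1b3 and Fabp3 were -0.22, -0.13 and -0.06; Fabp3 was -0.28 without control 2 or transgenic kidney 2 and -0.05 without transgenic kidney 1. Of the 9 macrophage and dendritic cell genes 8 were lower, with a median of -0.16 (camera adjusted p = 0.0113; adjusted p = 0.655 with an estimated correlation), among them the complement genes C1qa (-0.25), C1qb (-0.22) and C1qc (-0.22) and the class II gene H2-Ab1 (-0.10). C1qa, C1qb and C1qc were -0.15, -0.08 and -0.06 without transgenic kidney 1 and -0.39, -0.40 and -0.36 without transgenic kidney 3; C1qc and H2-Ab1 were -0.33 and -0.18 without control 1, and C1qa and H2-Ab1 were -0.06 and -0.04 without control 3. None of these 4 calls held with an estimated correlation. Each call was also lost without at least 1 library, namely the androgen-responsive list without control 1 (adjusted p = 0.0806) or transgenic kidney 1 (0.0579), the thick ascending limb without control 1 (0.0593), control 2 (0.0825) or transgenic kidney 1 (0.0579), the inner medulla without control 2 (0.150) or transgenic kidney 2 (0.175), and the macrophage list without control 2 (0.222), control 3 (0.0729) or transgenic kidney 1 (0.387), by camera.

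The renin angiotensin aldosterone list was not called in all genes (camera adjusted p = 0.0601; 0.459 with an estimated correlation) and was called with X and Y genes left out (camera adjusted p = 0.01002; 0.425 with an estimated correlation), with the stricter filter (0.0152; 0.374 with an estimated correlation), without control 3 (0.00470; 0.457 with an estimated correlation) and without transgenic kidney 2 (0.0108; 0.272 with an estimated correlation). Ren1 was its 1 member past the threshold adjusted over the list alone. The substrate gene Agt differed by 0.05 on the log2 scale, the converting enzyme gene Ace by -0.10 and the receptor gene Agtr1a by 0.02. The sodium channel genes Scnn1a, Scnn1b and Scnn1g, which respond to aldosterone, differed by 0.08, -0.03 and -0.22.

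No list of injury, stress or metabolic genes was called in the test of all genes fixed in advance. The tubular injury list had 9 measured members with a median log2 fold change of -0.05 (camera adjusted p = 0.471), among them Spp1 (-0.39), Clu (0.04) and Vim (0.23). The 30 proximal tubule genes had a median of 0.01 (0.471), with Lrp2, the megalin gene, at 0.01 and Slc34a1, a phosphate transporter gene, at 0.06. The 18 heat shock genes had a median of 0.00 (0.568), with Hspa8 at 0.09 and Hsp90aa1 at -0.10. Medians were -0.03 for the 17 unfolded protein response genes (0.568), 0.02 for the 21 oxidative stress and NRF2 genes (0.326), -0.04 for the 24 oxidative phosphorylation genes (0.470), 0.08 for the 19 genes of fatty acid oxidation and PPAR alpha (0.237), 0.06 for the 11 hypoxia genes (0.234) and 0.03 for the 11 fibrosis and matrix genes (0.449). Havcr1 and Lcn2, the kidney injury markers named in advance, are outside the 7373 listed genes and were not analysed here. The tubular injury list had 9 of its 27 genes measured, and the fibrosis and matrix list 11 of 24. Members outside the listed genes were not tested. The stress hormone target Fkbp5 differed by 0.04 ± 0.29 (SE) on the log2 scale, and by -0.28 without transgenic kidney 1 to 0.25 without transgenic kidney 2. With X and Y genes left out and a correction for GC content and length, fatty acid oxidation was called higher (camera adjusted p = 0.0411; adjusted p = 0.691 with an estimated correlation). Leaving out 1 library gave calls by camera at the preset correlation: the unfolded protein response was higher without control 3 (adjusted p = 0.0186) and lower without transgenic kidney 1 (0.0170), hypoxia was higher without control 3 (0.0466) or transgenic kidney 2 (0.0338), fatty acid oxidation was higher without control 3 (0.00470) or transgenic kidney 2 (0.00122), oxidative phosphorylation was lower without control 2 (0.0127), and the proximal tubule was lower without transgenic kidney 3 (0.0413). None of these passed with an estimated correlation, where the smallest adjusted p among them was 0.272.

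The following lists were not called in that test either. Medians were 0.01 for glucocorticoid response (camera adjusted p = 0.633), 0.06 for immediate early genes (0.277), 0.07 for the circadian clock (0.471), -0.09 for cholesterol and lipid synthesis (0.116), 0.01 for apoptosis and p53 (0.890), -0.03 for autophagy (0.633), -0.09 for interferon response (0.732) and -0.12 for acute phase and complement (0.933). Only 4 of 22 interferon genes and 4 of 21 acute phase and complement genes were measured. Among other cell types the medians were 0.00 for the distal convoluted tubule (0.483), -0.03 for principal cells (0.864), 0.08 for intercalated cells (0.163), 0.05 for endothelium (0.933), -0.14 for red blood cells (0.470) and -0.33 for adipocytes (0.483). Some were called when 1 library was left out, by camera at the preset correlation: adipocytes higher without control 2 (adjusted p = 0.000217), red blood cells lower without control 3 (9.29e-21), glucocorticoid response (0.0108) and circadian clock (0.0178) higher and cholesterol and lipid synthesis lower (0.00768) without transgenic kidney 2, and intercalated cells higher without transgenic kidney 3 (0.0488). None of these passed with an estimated correlation, where the smallest adjusted p among them was 0.156. Without control 3, Hba-a2 of the red blood cell list was at -3.24 and passed the edgeR test over all genes. With all libraries the other members outside X lay between -0.32 (Hbb-bs) and 0.14 (Slc25a37). How far Hba-a2 alone makes the red blood cell call was not tested. Outside the lists of this paragraph, Podxl, Clic5 and Cdkn1c, among 4 measured podocyte markers, differed by 0.23, 0.05 and -0.01. With X genes left out the glucocorticoid median was -0.01 and the red blood cell median -0.23. The median differed in sign from the mean or from the direction of the test in 7 lists: proximal tubule, distal convoluted tubule, endothelium, adipocyte, heat shock, apoptosis and p53, and autophagy. Lists with fewer than 4 measured members were not tested: Akr1b7 of the adrenal gland list differed by 0.44, Psca and Krt7 of the urothelium by -0.78 and -0.07, Npr1, Npr2 and Pde9a of the natriuretic peptide list by 0.09, 0.28 and 0.15, Cxcl12, Icam1 and Nfkbia of the cytokine list by -0.12, 0.19 and 0.07, Pcna, Tyms and Tk1 of the cell cycle list by -0.29, 0.25 and -0.29, and Igj of the lymphocyte list by -0.01. No gene of the skeletal and cardiac muscle list is among those listed, and Eif2s3y is the 1 measured gene of the sex check list.

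**Figure D3:**
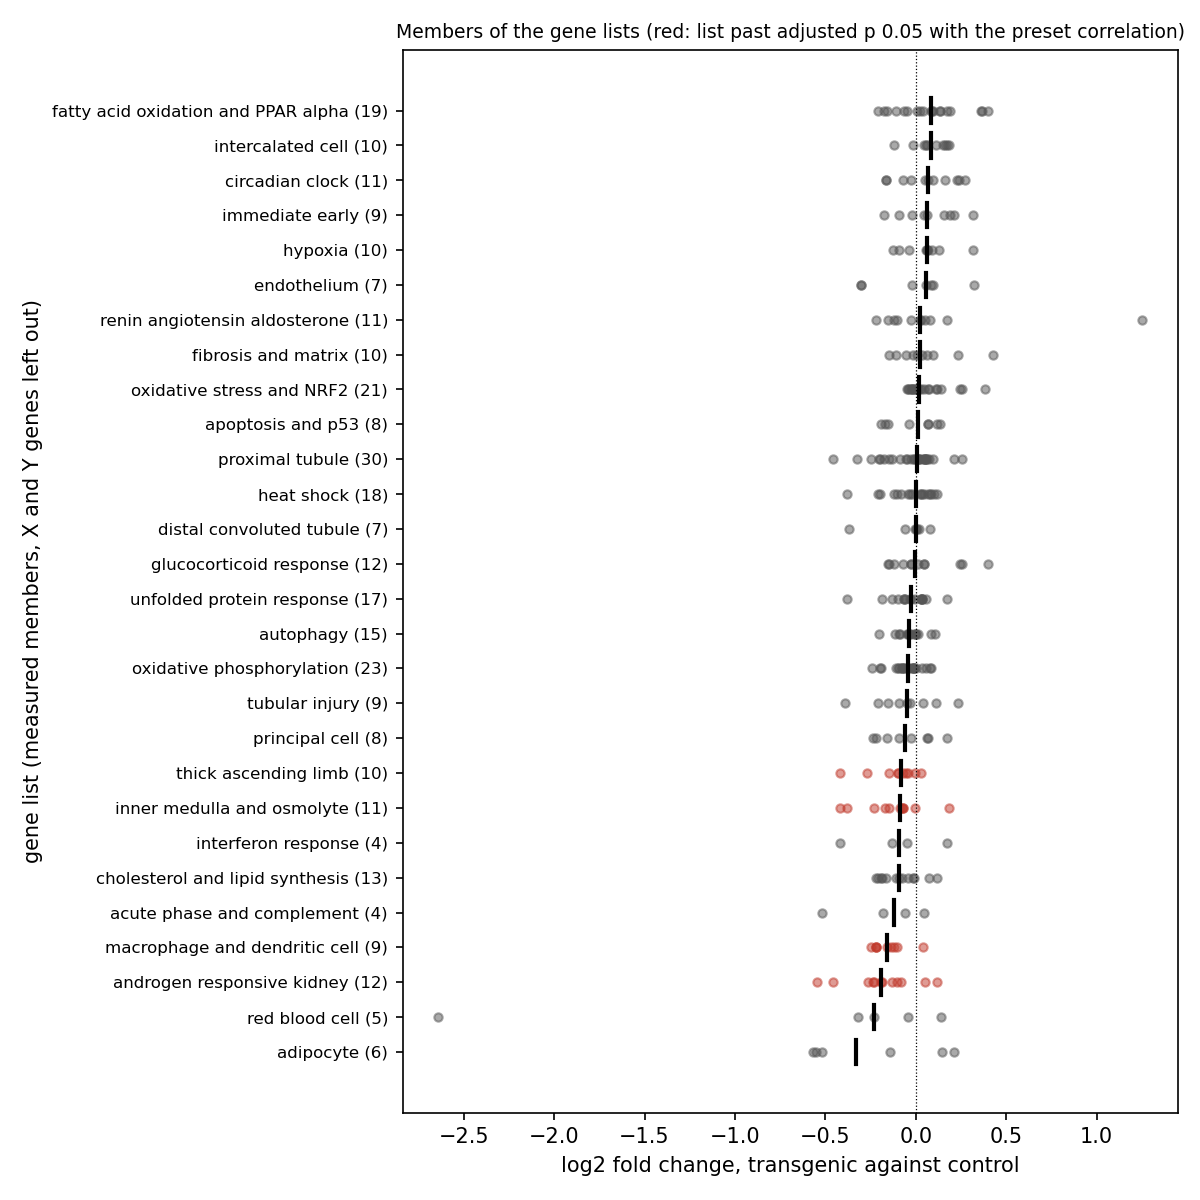
Log2 fold changes (transgenic against control, X and Y genes left out) of the measured members of the tested gene lists described here, 1 point per gene, with the list median as a black bar. Red lists are the 4 past an adjusted p of 0.05 with the preset correlation in the test that kept the X and Y genes, none of which passed with an estimated correlation; Ren1 in the renin angiotensin aldosterone list stands apart from the other members at 1.25.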

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

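Leaving out X and Y genes, alone or combined with another setting, and the authors' log2 values were chosen after the data were seen; the other settings were planned. The count of changed genes was 0 in the edgeR test of all genes (112 with an unadjusted p under 0.05) and stayed at 0 with DESeq2 size factors, no filter, the stricter filter, 1 row per gene, an adjusted p of 0.1 and a 1.5-fold minimum. It was 2 with DESeq2 and 1 with limma array weights. With X and Y genes left out it was 1 with edgeR, with a robust prior, at an adjusted p of 0.1, with the GC and length correction and with limma on the authors' log2 values, and 2 with DESeq2. Without 1 library it ranged from 0 to 2, and the 2 came without control 3, where Hba-a2 was called besides Ren1 (log2 fold change -3.24, adjusted p = 0.00596, edgeR). The genes at an unadjusted p under 0.05 numbered 38 without transgenic kidney 1, 448 without control 2 and 167 without control 3, and 47, 597 and 166 with X and Y genes left out as well. Hba-a2 may share reads with its near-identical copy Hba-a1. The prior degrees of freedom were 2.404 with the zeros and 4.44 without X and Y genes. Simulated zeros cut them from 12.4 to 3.26. The cause of other moves was not tested.

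The number of called lists was 5 and ranged from 2 to 11 without 1 library (with X and Y genes kept, 3 without control 1 or control 2, 9 without control 3, 2 without transgenic kidney 1 and 10 without transgenic kidney 2). It was 0 with an estimated correlation and 0 with the directional p of fry, with or without X and Y genes; the cause was not tested, and correlation alone does not account for it, since the thick ascending limb list has an estimated correlation of -0.0156, under the preset one.

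The labels state no pairing by replicate number. Deviations from the group means correlated at 0.00, -0.02 and 0.33 in kidneys of equal number. Controls 1 and 2 correlated better with another number and control 3 best with its own, so these values do not settle whether numbers pair the samples. With the replicate number as a block 0 genes and 5 lists were called; with X and Y genes left out 1 gene and 6 lists; with the GC and length correction as well 1 gene and 10 lists, among them intercalated cell (adjusted p = 0.0460), adipocyte (0.0465), oxidative stress (0.0367) and fatty acid oxidation (0.0367), all higher by camera and at 0.696 with an estimated correlation, against 7 lists without the block.

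Of 782 values of the 32 named genes under alternatives, 753 kept their direction and side of the threshold, 14 passed it (Ren1 in 12 of them) and 15 changed sign, all of genes near 0, where the cause was not tested. Cdkn1c was 0.11 with array weights and between -0.156 and 0.0902 without 1 library, Fkbp5 was -0.0151 with array weights, -0.0366 with the GC and length correction and the replicate block and between -0.28 and 0.25 without 1 library, and Clic5 lay between -0.0427 (without transgenic kidney 1) and 0.161 (without transgenic kidney 2). Cryab lay between -0.47 and -0.22 in all 26 alternatives, with an adjusted p of 0.578 or more. Quantile normalization, median centring and other pseudocounts were planned for normalized values and were not run on counts. No simulation varied depth. At this depth 56.8% of simulated 1.5-fold changes were recovered in complete counts and 24.4% with the zeros. Both shares may be too high, since real fits had fewer prior degrees of freedom.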

Other observations

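The list of renin cell and vascular smooth muscle genes, the list of glomerular genes, the tests on the zeros of control 3 and the test of GC content as the whole cause of its distance were chosen only after the results they bear on were seen. The bounds for the glomerular list were written before its values were looked at, but the requirement that its median lie beyond a bound by more than the SD of its members was applied only after that median was seen; by the bounds alone the list would argue against a gain of glomeruli. Besides the explanations weighed below, 3 further tests were run and are given by their values only: more vessel wall cells (median 0.09), a single control library behind Ren1 (lowest log2 fold change 1.14) and the zeros and the shrinkage of variances (prior degrees of freedom 2.404 against 4.44 without X and Y genes). Genes named here outside the lists were chosen after their values were seen.

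No gene named in this paragraph passed the edgeR test of all genes. Ehd3, a marker of glomerular endothelium, was higher in all 3 transgenic kidneys (28.6 ± 4.56 against 35.8 ± 2.02 CPM, SD, n = 3), and so was Sema3g, made by podocytes among other cells (log2 fold change 0.74 with X and Y genes left out). Plvap, a marker of peritubular capillaries, was lower in all 3 (log2 fold change -0.30). Akr1b7, an aldo-keto reductase made by renin cells, was higher in all 3, at 5.12 ± 0.615 CPM (SD, n = 3) in controls and 6.93 ± 0.660 (SD, n = 3) in transgenic kidneys. Of 10 measured renin cell and vascular smooth muscle genes, 9 were higher, with a median of 0.09 and a highest value of 0.43 at Akr1b7 (camera p = 0.000448 with the preset correlation, 0.0852 with an estimated one). Ren1 was not on that list. Of 14 measured glomerular genes 5 were higher and 9 lower, from -0.23 to 0.43, the highest being Col4a3 (camera p = 0.709 with the preset correlation, 0.787 with an estimated one).

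Cfd, Car3 and Hba-a2 differed widely between single kidneys. Thrsp of the adipocyte list had a wide error too (log2 fold change -0.57 ± 0.84, SE). Lpl of that list (0.14 ± 0.14, SE) and Bpgm of the red blood cell list (-0.04 ± 0.10, SE) varied less. Cfd, which encodes adipsin of fat cells, stood at 0.217, 76.0 and 0.0423 CPM in controls 1, 2 and 3 and at 28.3, 6.75 and 18.0 in the transgenic kidneys, and Car3 at 1.85, 38.8 and 0.867 against 10.8, 3.23 and 14.0. Hba-a2, an α-globin gene, stood at 13.9, 12.5 and 0.254 in the controls and at 1.04, 2.02 and 1.22 in the transgenic kidneys, while its near-identical copy Hba-a1 stood at 548, 474 and 227 against 326, 455 and 281.

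The zeros of X and Y genes in control 3 covered all 178 of these genes and no other gene. A low depth is argued against, since control 3 had the highest total of the 6 libraries, 47.6 M estimated counts. A female kidney would keep its X genes, yet their median count in control 3 was 0. Reads of both chromosomes missing from this column of the table could produce such a pattern, with 178 of 178 genes at 0; where they were lost was not tested. Without control 3, none of the 178 genes was called by edgeR, 4 had an unadjusted p under 0.05, and their median log2 fold change was 0.01.

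Control 3 lay apart from the other libraries in genes outside X and Y too, with a median absolute deviation of 0.205 on the log2 scale against 0.0723 to 0.115 in the others. Depth is argued against, because after thinning all libraries to the smallest total the first component still held 52.2% with control 3 as its extreme. Across genes, which are not independent replicates, its deviation followed GC content with a Spearman rho of -0.55. GC content and length are argued against as the whole cause, since after their correction the first component held 44.7% and control 3 was still its extreme. They may be part of it, which cannot be told apart here, because the fall of 7.11 points was smaller than the 10 points set in advance while the rho was large; a difference of this animal stays open, as untested.

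The higher Ren1 in transgenic kidneys may come from the transgenic state or from the pieces sampled. GC content and length are argued against for Ren1, whose log2 fold change was 1.22 after their correction. More glomeruli or more cortex in the transgenic pieces as the whole cause would need podocyte genes near 1.25. The median of the podocyte list was 0.14, which argues against that cause only weakly. It rests on 4 measured members and does not describe each of them. The lower lists of the thick ascending limb and inner medulla go with a shift toward cortex. A smaller gain of glomeruli cannot be told apart from none, since the 14 glomerular genes had a median of -0.0343 with an SD of 0.173 and several are also made by tubules. More renin per cell, more renin-making cells without other vessel wall cells and an effect of the heart on the kidney stay open, as untested.

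The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In the edgeR test of all genes the real split called 0 (112 at an unadjusted p under 0.05; 2 with DESeq2, 1 with limma), all 10 splits called as many or more, and the highest other called 1. With X and Y genes left out the real split called 1 gene, 2 of the 10 splits called as many or more, and the highest other, controls 2 and 3 with transgenic kidney 3 against the rest, called 3. For gene lists the real split called 5, 7 splits called as many or more, and the highest other called 9. Other splits gave up to 587 genes with an unadjusted p under 0.05 with X and Y genes left out, against 131 in the real one, which points to structure among the libraries other than the genotype.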
